A study of Arabidopsis thaliana with 15 samples.

How the data were processed

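Root RNA of Arabidopsis thaliana wild-type seedlings (ecotype Columbia-0, 7 d old) was measured in 15 libraries. Per the labels' protocols, seedlings grew on Murashige and Skoog medium with 1% sucrose and 0.8% agar at 21 °C in 16 h of light and 8 h of dark, each biological replicate held 30 to 50 seedlings, and roots were parted from shoots after the treatment. RNA was extracted with Trizol, and libraries were made by MARS-seq, which tags the 3' ends of poly(A) RNA and adds unique molecular identifiers (UMIs), and were read on an Illumina NextSeq instrument with a 75 cycle kit. How the UMIs were treated is not given in the sources used here, so counting errors apply to counts as deposited and molecules cannot be told from amplified copies.

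The submitters' processing notes name bcl2fastq, cutadapt, STAR 2.4.2a, HTSeq and DESeq2, and give the tools no role or order. The genome build and the annotation behind the counts are not given in the sources used here. The deposited table lists 14532 genes with 45 per-sample columns, of which the 15 columns of raw counts were used. The other 30, the normalized and the log-transformed values made by the authors, were not used here. For each of the 6 comparisons the authors' deposited columns hold a log2 fold change, a p-value, an adjusted p-value and a yes or no call. These deposited log2 fold changes, p-values and calls were set beside the recomputed ones and entered no fit. The lowest of the listed genes' maximum counts was 6, so the table is a filtered list of genes.

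The 5 groups of 3 replicates came from the sample titles and treatment fields. Water samples carry time 0 in their title and water for 1 h in their treatment field, so only the 1 h comparison has a control of the same stated time, and in the others H2O2 and time in solution differ together. The second compound is written RB in the titles and MRB in a treatment field, and the series title names Rose Bengal, a dye that forms singlet oxygen in light. Samples with RB alone and water samples of other times were not analysed here, so the effect of RB without H2O2 has no value here. What the replicate letters mark is not given in the sources used here, and they were not taken as pairs in the main fit. Over 30 pairs of libraries with the same letter, the correlation of residual log2 CPM ran from -0.44 to 0.64. Of 15 libraries, 7 were closest to one of their own letter. These values do not settle whether libraries of a letter were handled together.

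Counts were fitted with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr by group (minimum count 10, minimum total 15), which left 9986 genes and set 4546 aside as not tested. TMM factors ran from 0.784 to 1.20. One quasi-likelihood negative binomial model (glmQLFit, robust, no intercept, a term per group) held all 15 libraries and left 10 residual degrees of freedom. Each contrast was tested with glmQLFTest, two-sided, with Benjamini-Hochberg adjustment (BH) over the genes tested, and a call is an adjusted p under 0.05. The SE of a log2 fold change is its size over the root of its quasi-likelihood F. Log2 CPM values used a prior count of 2, and CPM values, which are counts scaled to one common library total with TMM, are given as mean ± SD over 3 libraries. Every adjusted p of a gene below comes from this edgeR model with BH.

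Total counts per library ran from 689372 to 6231140. The median SE of a log2 fold change over the genes tested was 0.38, 0.38, 0.36, 0.37, 0.37 and 0.37 in the 6 comparisons, the common biological coefficient of variation was 0.272, and replicates correlated in log2 CPM at 0.890 to 0.969. Within pairs of replicates the squared differences, averaged over genes, exceeded Poisson sampling 4.80 to 30.1 times. On this average counting error was the smaller part of the spread, which need not hold for genes with few counts. On data simulated from the water libraries with 200 changed genes, a true log2 change of 1 was called for 6.56% to 26.7% of genes, a change of 2 for 72.6% to 88.9% and a change of 3 for 92.2% to 96.8%, and 0.82% to 6.84% of the calls were false. The comparisons with water gave more calls than these 200, and BH is less strict where more genes change, so the shares called may be understated for them. Counts were drawn gene by gene with the fitted dispersions, so no spread was shared among genes. The share of false calls thus leaves out error from such shared spread and may be higher in the real libraries.

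Gene lists were written from general knowledge of Arabidopsis before the data were examined, as were the comparisons, the tests, the thresholds and the rule for naming genes. Of 25 lists, 24 were tested as sets and 1, the sentinel genes, was read gene by gene. List counts below are out of the members tested, and each set was larger as written. Tested were 15 of 22 xenobiotic, 4 of 14 DNA damage and 10 of 20 WRKY genes. So were 23 of 41 glutathione S-transferase, 7 of 11 root hair and 4 of 13 salicylate genes. The filter keeps a gene with enough counts in 1 group alone. Members low in every group, or not listed in the deposited table, were left out. The sets were zinc-finger, ERF and kinase genes that respond to reactive oxygen species (ROS), WRKY transcription factors, singlet oxygen-responsive genes, glutathione S-transferases, antioxidant enzymes, heat shock proteins and factors, jasmonate genes, ethylene genes, tryptophan-derived defence metabolism, salicylate and pathogen defence, mitochondrial stress genes, xenobiotic detoxification, endoplasmic reticulum stress, the 26S proteasome, cytosolic ribosomal proteins, a cell death list of metacaspases, vacuolar processing enzymes and regulators, DNA damage response, cell cycle and division, aquaporins, photosynthesis genes as a mark of shoot tissue, and markers of root hair and epidermis, endodermis and cortex, stele, and root tip. Set tests used camera (limma 3.58.1, two-sided, against the other genes) with a preset correlation of 0.01, with BH over the 24 lists of a comparison, and again with an estimated correlation. In each case the set's adjusted p is from camera. The self-contained test fry was also run on the lists, and its p-values, which do not compare a list with other genes, are not reported here. Of the tested genes, some stand in 2 lists: UGT74E2 and CYP81D8 are mitochondrial and xenobiotic genes, LOX3 and OPR3 singlet oxygen and jasmonate genes, WRKY33, WRKY40 and WRKY53 WRKY and singlet oxygen genes, ERF5, ERF6 and ERF109 ROS and singlet oxygen genes, ERF1 and ERF2 ROS and ethylene genes, and HSP23.5 a heat shock and mitochondrial gene.

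Genes were named by rule: every sentinel, the 8 largest rises and 6 largest falls among called genes with a mean of at least 20 CPM and all 3 replicates of one group beyond all 3 of the other, and up to 3 called members of each list with the smallest adjusted p. Not every gene that this rule picked is described below. Other genes are said to have been chosen after their values were seen. The sentinels OXI1 and JAZ10 were not among the genes tested, and JAZ10 is not listed in the deposited table. The calls of single endodermis and cortex markers are not reported here. Symbols and products came from a reference gene table of the assembly TAIR10.1, which held 14497 of the listed identifiers, and 35 organellar genes were matched by identifier alone. Transcript lengths, of the longest annotated transcript, were found for 9963 tested genes. No coordinates are given because the authors' build is unnamed. Members of families with near-identical copies, among them extensins, small heat shock proteins, glutathione S-transferases and allene oxide cyclases, share sequence near the 3' end, and how shared reads were assigned is not given in the sources used here, so values of single members are uncertain.

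Alternatives fixed before the data were examined were scaling by RLE or upper quartile, no filter and a strict filter of 10 CPM, DESeq2 1.42.0, a fit to only the 6 samples compared, the replicate letter as a block, camera with an estimated correlation, and leaving out each replicate in turn. Added after the data were seen were a covariate of log2 total count, thinning of each library to 680000 counts, and offsets that remove each library's trend with transcript length. Thinning drew counts without replacement, in place of an edgeR function used first that removes them with replacement and so adds noise to deep libraries. Splits of the 6 samples of a comparison into other groups of 3 were fitted the same way. Figures were drawn with matplotlib 3.10.9.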

Results

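RNA from Arabidopsis roots was counted gene by gene in 5 groups of 3 biological replicates, written a, b and c. Roots were kept in water for 1 h, in 5 mM hydrogen peroxide (H2O2) for 1 h, 2 h or 3 h, or in 5 mM H2O2 with 10 µM RB for 2 h. RB is taken from the labels, and the series title names Rose Bengal, a photosensitizer. The total counts of replicates a, b and c were 2291529, 5073443 and 1219400 in water, 1115902, 4464761 and 689372 at 1 h of H2O2, and 2456784, 1093238 and 1277436 at 2 h. They were 4080521, 2793258 and 2580683 at 3 h, and 1500459, 1705965 and 6231140 with RB. The most abundant transcript, ATMG00020, took 0.809% to 3.998% of the counts of a library.

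Of 9986 genes tested, 958 changed at 1 h of H2O2 against water, 1392 at 2 h and 3048 at 3 h. With RB, 2120 genes changed against water and 243 against H2O2 alone at the same time, and 1383 genes differed between 3 h and 1 h of H2O2. An absolute log2 fold change of at least 1 was reached by 740, 1054, 2326, 1651, 222 and 1108 of these calls, in the same order.

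**Figure D1:**
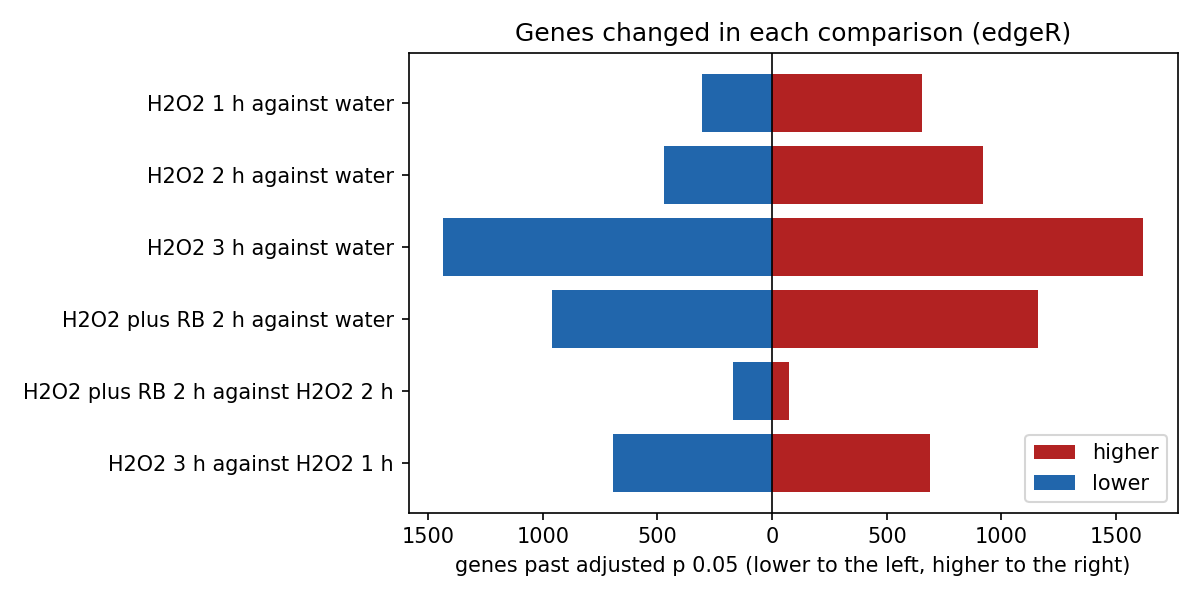
Bars give the number of genes higher (right) and lower (left) at an adjusted p under 0.05 in each of the 6 comparisons, with 3 libraries per group. At 3 h against water 1615 genes were higher and 1433 lower, and with RB against H2O2 alone 74 were higher and 169 lower.

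The comparison of 1 h of H2O2 with 1 h of water asks for the first response of the root to the oxidant. Transcription factor and heat shock genes were among the largest rises. ERF109 (AT4G34410), a redox-responsive transcription factor gene, rose to 164 ± 12.7 CPM from 10.3 ± 1.77 CPM in water (mean ± SD, n = 3 per group), a log2 fold change of 4.04 ± 0.34 (SE, adjusted p = 4.92e-07). A pair of related AP2/ERF-type genes, AT1G22810 and AT1G71520, rose by 5.26 ± 0.46 (adjusted p = 6.02e-07) and 5.15 ± 0.45 (adjusted p = 5.63e-07) on the log2 scale. The chaperone gene HSP101 (AT1G74310) rose to 178 ± 12.8 CPM from 17.65 ± 4.60 CPM (log2 3.37 ± 0.27, adjusted p = 4.4e-07), and its regulator HSFA2 (AT2G26150) rose by log2 4.26 ± 0.42 (adjusted p = 1.92e-06, and log2 6.56 with libraries thinned to equal depth). The oxophytodienoate reductase gene OPR1 (AT1G76680), a detoxification gene, rose to 1553 ± 345 CPM from 145.5 ± 55.4 CPM (log2 3.43 ± 0.31, adjusted p = 9.01e-07).

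At 1 h 654 genes were higher and 304 lower. The fallers were led by HOL2 (AT2G43920), a methyltransferase gene, at 3.58 ± 1.73 CPM against 53.3 ± 8.81 CPM (log2 -3.70 ± 0.38, adjusted p = 2.44e-06). They held the circadian gene ELF4 (AT2G40080, log2 -2.55 ± 0.27, adjusted p = 4.27e-06) and the cation exchanger gene CHX17 (AT4G23700, log2 -2.47 ± 0.35, adjusted p = 9.01e-05). Of the sentinel genes of oxidative stress, WRKY33 (AT2G38470), WRKY40 (AT1G80840), APX2 (AT3G09640) and GSTU24 (AT1G17170) rose by log2 1.05 ± 0.20, 1.69 ± 0.21, 3.45 ± 0.43 and 1.83 ± 0.39 (adjusted p = 0.00182, 2.38e-05, 1.99e-05 and 0.00469). Sentinels that did not pass were ZAT12 (AT5G59820, log2 0.97 ± 0.32, adjusted p = 0.0622, but called in 7 of 25 alternatives, among them DESeq2, thinning and without H2O2 3 h a or H2O2 3 h c) and the catalase genes CAT1 (adjusted p = 0.908) and CAT2 (adjusted p = 0.2). Nor did APX1 (adjusted p = 0.834), AOX1A (adjusted p = 0.819) and UGT74E2 (log2 -0.29, adjusted p = 0.886, but called at log2 2.05 without water a) pass. The calls numbered 577 without water a (365 higher), 634 without water b (394 higher) and 597 without H2O2 1 h a (157 lower).

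Heat shock genes rose as a group at 1 h. Of 34 heat shock proteins and factors tested, 23 rose and 11 did not pass (24 rose adjusted over the list alone), with a median log2 fold change of 2.19. Their set test gave adjusted p = 1.17e-40, and adjusted p = 0.00631 with an estimated correlation. Of 15 xenobiotic detoxification genes, 11 rose, and 11 adjusted over the list alone (median 2.19, adjusted p = 3.8e-25, and adjusted p = 0.00286 with an estimated correlation), among them UGT73B3 (AT4G34131, log2 3.14 ± 0.26, adjusted p = 4.92e-07). Singlet oxygen-responsive genes rose for 12 of 18, and 13 adjusted over the list alone (median 1.31, adjusted p = 7.7e-17, and adjusted p = 0.00631 with an estimated correlation).

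Further groups passed at 1 h with the preset correlation alone. Of 23 glutathione S-transferase genes, 8 rose and 1 fell, against 9 and 1 adjusted over the list alone (adjusted p = 6.32e-06, and adjusted p = 0.0668 with an estimated correlation). GSTU12 (AT1G69920) rose to 106 ± 13.95 CPM from 13.2 ± 7.20 CPM. Of 14 ROS-responsive zinc-finger, ERF and kinase genes 6 rose and 1 fell, against 9 and 1 adjusted over the list alone (adjusted p = 1.31e-06, and adjusted p = 0.131 with an estimated correlation). The 13 genes of tryptophan-derived defence metabolism held 6 that rose, or 9 adjusted over the list alone (adjusted p = 0.000761, and adjusted p = 0.0711 with an estimated correlation). Of 25 jasmonate genes 7 rose, and 7 adjusted over the list alone (adjusted p = 0.00343, and adjusted p = 0.0668 with an estimated correlation), with the lipoxygenase gene LOX4 (AT1G72520) at log2 3.50 ± 0.55 (adjusted p = 0.00029). Root hair and epidermis markers fell for 6 of 7, and 6 adjusted over the list alone (median -1.79, adjusted p = 2.14e-07, and adjusted p = 0.0668 with an estimated correlation). Their expansin gene EXPA7 (AT1G12560) had 8.01 ± 3.68 CPM against 54.5 ± 11.03 CPM (log2 -2.75 ± 0.48, adjusted p = 0.000795).

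**Figure D2:**
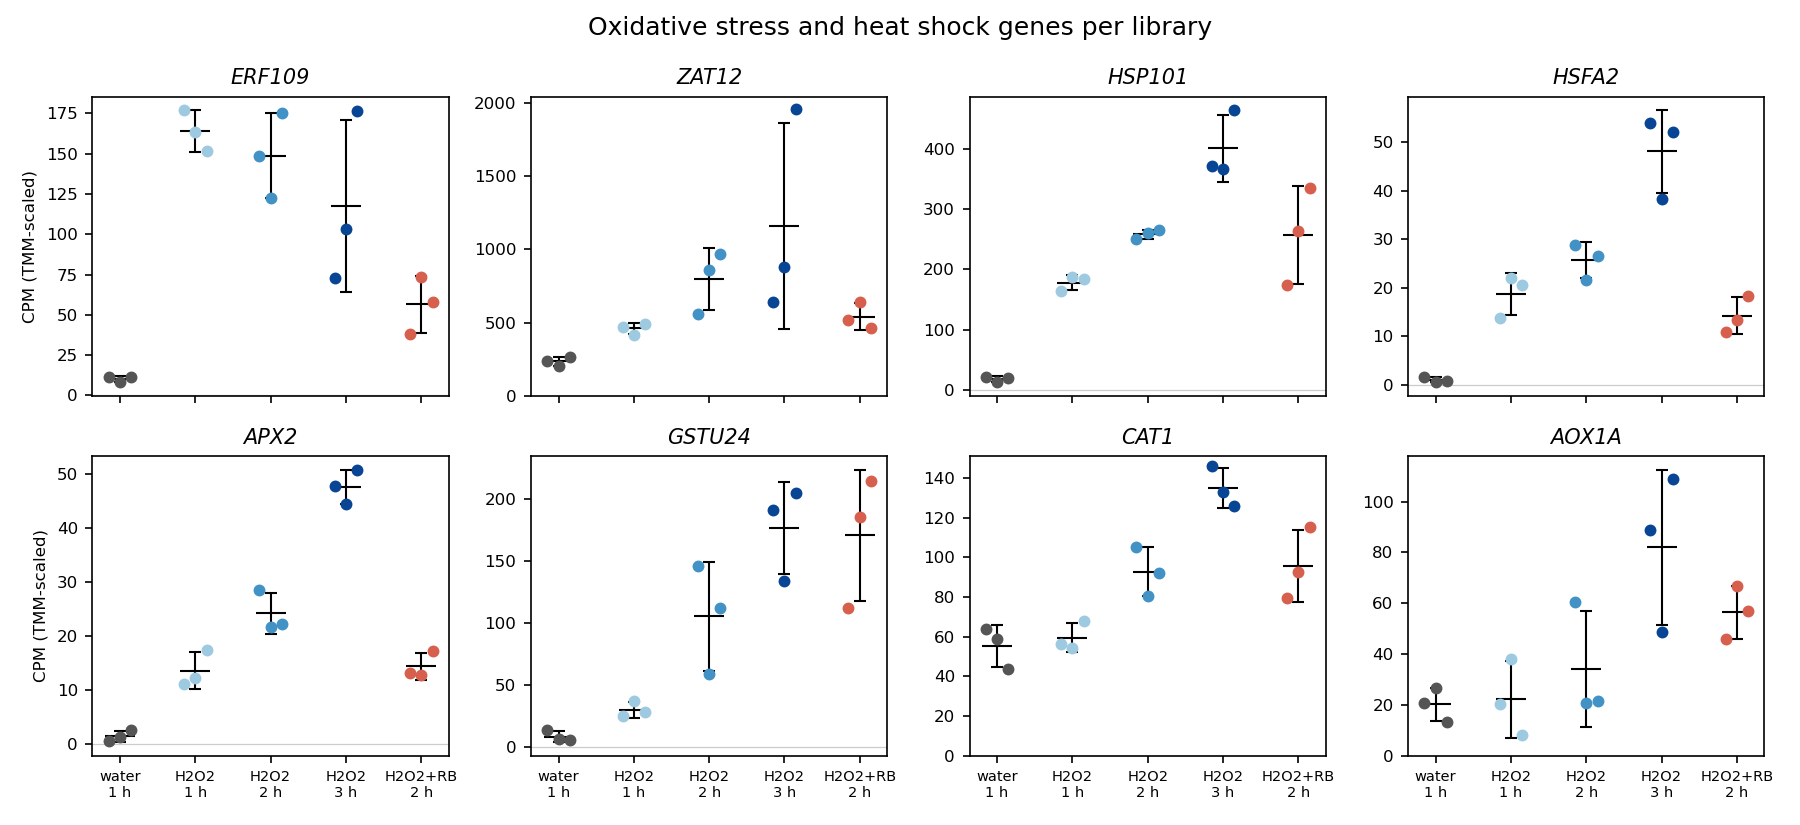
TMM-scaled CPM of 8 sentinel genes is plotted per library on the vertical axis for the 5 groups, with points for the 3 libraries, a horizontal mark for the mean and bars for the SD. ERF109 stood at 10.3 CPM in water and 164 CPM at 1 h of H2O2, and HSP101 at 17.65 CPM in water and 401 CPM at 3 h.

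The comparison of 2 h of H2O2 with water asks how the response went on, with a control whose stated time in water is 1 h. Small heat shock protein genes were among the largest rises, and genes of the cell wall were among the largest falls. HSP17.7 (AT5G12030) rose to 1031 ± 308 CPM from 19.4 ± 5.73 CPM (n = 3 per group), a log2 fold change of 5.79 ± 0.44 (adjusted p = 5.07e-08). OPR1 rose to 2677 ± 893.5 CPM (log2 4.21 ± 0.32, adjusted p = 5.07e-08), and the glucosyltransferase gene UGT75B1 (AT1G05560) rose by log2 4.67 ± 0.35 (adjusted p = 5.07e-08). The arabinogalactan protein gene AGP3 (AT4G40090) fell to 29.4 ± 12.04 CPM from 403 ± 94.3 CPM (log2 -3.80 ± 0.54, adjusted p = 6.42e-05).

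At 2 h 920 genes were higher and 472 lower. Sentinels called at this time included ERF109 (log2 3.89 ± 0.34, adjusted p = 2.17e-07), ZAT12 (log2 1.76 ± 0.32, adjusted p = 0.000893) and GSTU24 (log2 3.61 ± 0.39, adjusted p = 2.22e-06). CAT2, APX1, AOX1A (log2 0.78, adjusted p = 0.285, but called with the log2 depth covariate) and UGT74E2 (log2 1.25, adjusted p = 0.228, but called at log2 3.60 without water a) did not pass. The cyclin-dependent kinase inhibitor gene SMR5 (AT1G07500), which takes part in the DNA damage response, rose by log2 3.70 ± 0.53 (adjusted p = 7.35e-05). The calls numbered 914 without water b (582 higher) and 893 without H2O2 2 h c (602 higher, 291 lower), and 577 higher genes were left without water a.

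Of the lists at 2 h, heat shock genes rose for 25 of 34, and 29 adjusted over the list alone (median 3.23, adjusted p = 1.53e-52, and adjusted p = 0.00373 with an estimated correlation). Xenobiotic genes rose for 14 of 15, and 14 adjusted over the list alone (median 2.76, adjusted p = 5.44e-36, and adjusted p = 0.000607 with an estimated correlation). Singlet oxygen-responsive genes rose for 12 of 18, and 13 adjusted over the list alone (adjusted p = 1.44e-14, and adjusted p = 0.00675 with an estimated correlation). Glutathione S-transferase genes rose for 13 of 23, against 14 that rose and 1 that fell adjusted over the list alone (median 2.13, adjusted p = 4.58e-12, and adjusted p = 0.0126 with an estimated correlation). Root hair markers fell for 6 of 7, and 6 adjusted over the list alone (median -3.05, adjusted p = 3.84e-11, and adjusted p = 0.0139 with an estimated correlation). Of the ROS-responsive zinc-finger, ERF and kinase genes 10 of 14 rose and 1 fell, with the same counts adjusted over the list alone (adjusted p = 1.37e-08, and adjusted p = 0.0843 with an estimated correlation). Tryptophan-derived defence genes rose for 6 of 13, and 8 adjusted over the list alone (adjusted p = 0.000828, and adjusted p = 0.0777 with an estimated correlation). Jasmonate genes rose for 6 of 25, and 6 adjusted over the list alone (adjusted p = 0.029, and adjusted p = 0.0986 with an estimated correlation).

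The comparison of 3 h of H2O2 with water covers the longest exposure. Chaperone genes were among the largest rises, and extensin genes of the cell wall among the largest falls. HSP17.7 reached 3181 ± 2040 CPM against 19.4 ± 5.73 CPM in water (n = 3 per group, log2 7.41 ± 0.47, adjusted p = 3.27e-09), and HSP101 reached 401 ± 55.2 CPM (log2 4.54 ± 0.28, adjusted p = 3.27e-09). The hypoxia-responsive factor gene ERF71 (AT2G47520) rose by log2 5.20 ± 0.54 (adjusted p = 9.24e-07), and CYP81D8 (AT4G37370), a marker of mitochondrial and xenobiotic stress, by log2 5.43 ± 0.42 (adjusted p = 2.82e-08). The extensin-like gene AT3G28550 fell to 6.77 ± 8.53 CPM from 295 ± 83.9 CPM (log2 -5.26 ± 0.77), and HRGP1 (AT3G54590), of the same class, fell by 7.08 ± 0.92 on the log2 scale (adjusted p = 1.42e-05).

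At 3 h 1615 genes were higher and 1433 lower, so that 53.0% of the calls were higher. With upper-quartile scaling the fold changes of all genes shifted by a median of -0.16 and 41.0% of the calls were higher, so the balance of rises and falls depended on the scaling. Sentinels that passed at 3 h included CAT1 (AT1G20630, log2 1.28 ± 0.22, adjusted p = 0.000208), AOX1A (AT3G22370, log2 1.97 ± 0.44, adjusted p = 0.00223) and UGT74E2 (AT1G05680, log2 2.398 ± 0.62, adjusted p = 0.00637, and log2 4.79 without water a). ZAT12 (log2 2.30 ± 0.33, adjusted p = 3.51e-05) and BAP1 (AT3G61190, log2 1.89 ± 0.32, adjusted p = 0.000219) passed as well. APX1 (adjusted p = 0.22) and CAT2 (log2 -0.62, adjusted p = 0.0649, but called in 6 of 25 alternatives, among them upper-quartile scaling and without H2O2 2 h a or H2O2 3 h a) did not pass. The cell cycle inhibitor genes SMR5 and SMR7 (AT3G27630) rose by log2 5.52 ± 0.51 (adjusted p = 2.01e-07) and 3.31 ± 0.54 (adjusted p = 0.000132).

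Among the lists at 3 h, heat shock genes rose for 30 of 34, and 30 adjusted over the list alone (median 3.90, adjusted p = 1.99e-47, and adjusted p = 0.00662 with an estimated correlation). All 15 xenobiotic genes tested rose, and 15 adjusted over the list alone (median 3.25, adjusted p = 1.4e-28, and adjusted p = 0.00269 with an estimated correlation). Singlet oxygen-responsive genes rose for 13 of 18, against 14 that rose and 1 that fell adjusted over the list alone (adjusted p = 2.58e-10, and adjusted p = 0.0233 with an estimated correlation). Glutathione S-transferase genes rose for 13 of 23 and fell for 2, against 14 and 2 adjusted over the list alone (adjusted p = 3.74e-09, and adjusted p = 0.0245 with an estimated correlation). Tryptophan-derived defence genes rose for 9 of 13, and 10 adjusted over the list alone (median 1.51, adjusted p = 2.1e-06, and adjusted p = 0.0233 with an estimated correlation). Mitochondrial stress genes rose for 5 of 11, and 5 adjusted over the list alone (adjusted p = 2.46e-05, and adjusted p = 0.0245 with an estimated correlation). WRKY factors rose for 7 of 10, and 7 adjusted over the list alone (adjusted p = 0.000198, and adjusted p = 0.0459 with an estimated correlation).

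All 7 root hair and epidermis markers tested fell at 3 h, and 7 adjusted over the list alone (median -2.76, adjusted p = 3.74e-09, and adjusted p = 0.0251 with an estimated correlation). EXPA7 had 3.29 ± 1.14 CPM, and the proline-rich protein gene PRP3 (AT3G62680) fell by 5.09 ± 0.63 on the log2 scale (adjusted p = 7.33e-06). The ROS-responsive zinc-finger, ERF and kinase genes rose for 11 of 14, and 11 adjusted over the list alone (adjusted p = 3.78e-10, and adjusted p = 0.0622 with an estimated correlation). Of 4 DNA damage genes tested, 3 rose, and 3 adjusted over the list alone (adjusted p = 0.00235, and adjusted p = 0.0509 with an estimated correlation).

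**Figure D3:**
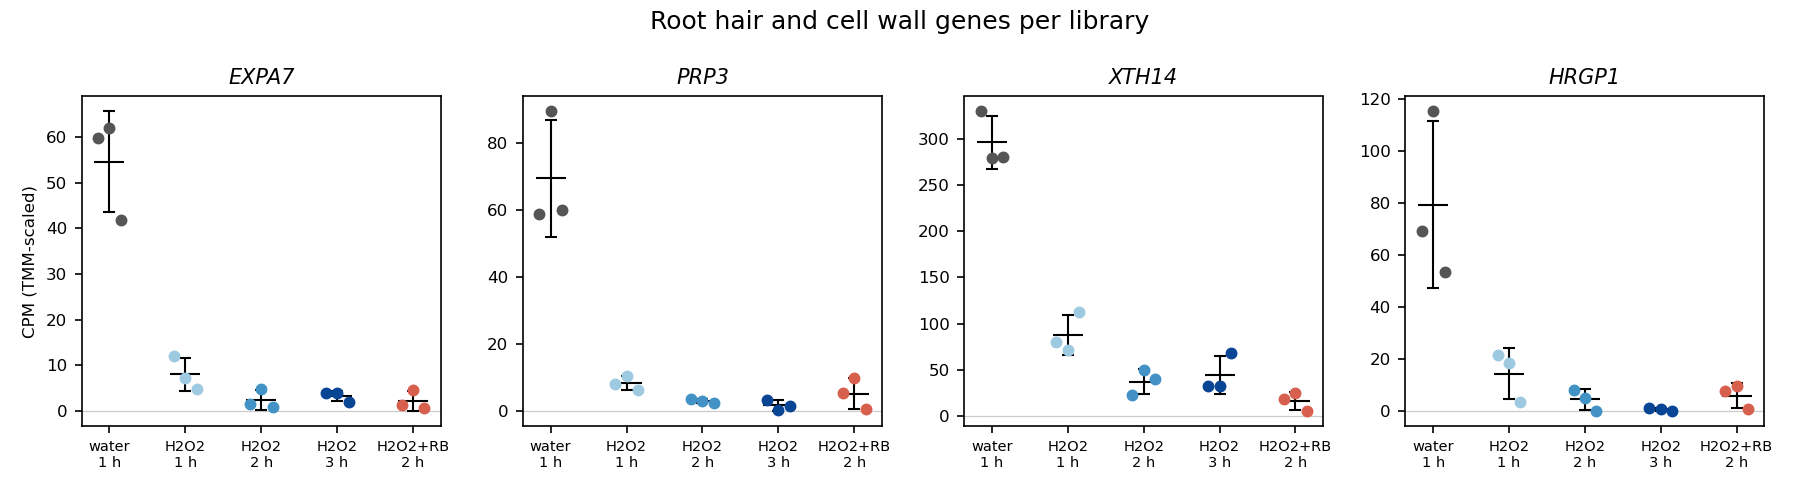
TMM-scaled CPM of EXPA7, PRP3, XTH14 and HRGP1 is plotted per library on the vertical axis for the 5 groups, with points for the 3 libraries, a horizontal mark for the mean and bars for the SD. EXPA7 stood at 54.5 CPM in water, 8.01 CPM at 1 h of H2O2 and 3.29 CPM at 3 h.

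The comparison of 3 h with 1 h of H2O2 asks which transcripts went on changing within the treatment. Some glutathione S-transferase genes, heat shock genes and cell cycle inhibitor genes were higher at 3 h than at 1 h, and extensin genes were among those lower. GSTF2 (AT4G02520) rose to 2515 ± 26.3 CPM from 652 ± 145 CPM (n = 3 per group, log2 1.95 ± 0.25, adjusted p = 4.66e-05). AT1G73120 rose to 188 ± 88.7 CPM from 6.78 ± 1.35 CPM (log2 4.84 ± 0.50, adjusted p = 8.63e-06). The protease inhibitor gene KTI1 (AT1G73260), lower at 1 h than in water (log2 -2.27 ± 0.34, adjusted p = 0.000159), rose to 2399 ± 1457 CPM from 360 ± 15.6 CPM (log2 2.73 ± 0.34, adjusted p = 4.53e-05). NIT4 (AT5G22300), for a nitrilase, rose by log2 3.26 ± 0.44 (adjusted p = 9.36e-05). The coatomer gene AT4G31480 fell by 3.96 ± 0.39 on the log2 scale (adjusted p = 6.9e-06).

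Between 1 h and 3 h 690 genes were higher and 693 lower, and 49.9% of the calls were higher. Upper-quartile scaling gave a median shift of -0.12 and 38.1% higher calls. Among the early genes, ERF109 (log2 -0.49, adjusted p = 0.275, but called at -0.91 without H2O2 3 h c), WRKY33 (log2 0.42, adjusted p = 0.168) and WRKY40 (log2 -0.04, adjusted p = 0.926) did not pass. HSP101 (log2 1.17 ± 0.24, adjusted p = 0.00323), APX2 (log2 1.87 ± 0.31, adjusted p = 0.000587) and CAT1 (log2 1.2015 ± 0.22, adjusted p = 0.00147) rose. ZAT12 rose by log2 1.33 ± 0.32 (adjusted p = 0.00912), a call lost without H2O2 3 h c. The calls numbered 749 without H2O2 1 h a (356 higher, 393 lower), 908 without H2O2 3 h b (397 lower) and 753 without H2O2 3 h c (345 higher, 408 lower).

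Of the lists, 9 of 24 passed between 1 h and 3 h, and the lowest adjusted p with an estimated correlation was 0.0734. Heat shock genes rose for 22 of 34, against 26 that rose and 2 that fell adjusted over the list alone (median 1.36, adjusted p = 1.78e-22, and adjusted p = 0.0734 with an estimated correlation). Xenobiotic genes rose for 8 of 15, and 10 adjusted over the list alone (adjusted p = 4.38e-09, and adjusted p = 0.0734 with an estimated correlation). Mitochondrial stress genes rose for 6 of 11, against 7 that rose and 1 that fell adjusted over the list alone (adjusted p = 0.000349, and adjusted p = 0.0734 with an estimated correlation). Glutathione S-transferase genes rose for 9 of 23 and fell for 1, against 9 and 2 adjusted over the list alone (adjusted p = 0.00016, and adjusted p = 0.179 with an estimated correlation). The ROS-responsive zinc-finger, ERF and kinase genes rose for 5 of 14, and 9 adjusted over the list alone (adjusted p = 0.00016, and adjusted p = 0.26 with an estimated correlation). Root hair markers fell for 3 of 7, and 7 adjusted over the list alone (adjusted p = 0.00152, and adjusted p = 0.22 with an estimated correlation). Tryptophan-derived defence genes rose for 5 of 13, and 5 adjusted over the list alone (adjusted p = 0.00337, and adjusted p = 0.17 with an estimated correlation). Endoplasmic reticulum stress genes fell for 4 of 12, and 6 adjusted over the list alone (median -0.51, adjusted p = 0.0122, and adjusted p = 0.209 with an estimated correlation). The singlet oxygen-responsive list had a median of 0.10 and a mean of -0.03 and did not pass (adjusted p = 0.5, test upward).

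The comparison of H2O2 plus RB with water gives the response to the combined treatment. The glutathione S-transferase gene GSTU12 was among the largest rises, genes of camalexin and jasmonate synthesis also rose, and genes of the cell wall and of aquaporins were among those that fell. GSTU12 rose to 778.5 ± 92.4 CPM from 13.2 ± 7.20 CPM (n = 3 per group, log2 6.02 ± 0.35, adjusted p = 5.37e-09). The camalexin synthesis gene PAD3 (AT3G26830) rose by log2 4.68 ± 0.44 (adjusted p = 2.94e-07), and the allene oxide cyclase gene AOC2 (AT3G25770) by log2 4.62 ± 0.41 (adjusted p = 1.91e-07). The cell wall enzyme gene XTH14 (AT4G25820) fell to 15.9 ± 9.55 CPM from 297 ± 28.8 CPM (log2 -4.35 ± 0.45, adjusted p = 1.01e-06). The aquaporin gene PIP2-4 (AT5G60660) fell to 25.6 ± 10.9 CPM from 121 ± 22 CPM (log2 -2.30 ± 0.29, adjusted p = 1.01e-05).

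With RB 1159 genes were higher and 961 lower than in water. HSP101 (log2 3.91 ± 0.28, adjusted p = 1.66e-08), HSFA2 (log2 3.88 ± 0.42, and 6.29 with thinning) and ERF109 (log2 2.503 ± 0.33, adjusted p = 1.91e-05) rose. So did BAP2 (AT2G45760, log2 4.69 ± 0.50, adjusted p = 1.27e-06), a gene of the singlet oxygen list, while its relative BAP1 did not pass (log2 0.30 ± 0.32, adjusted p = 0.564). The call of ZAT12 (log2 1.204 ± 0.32, adjusted p = 0.00976) was lost without RB b. The ethylene response factor gene ERF72 (AT3G16770) fell by 2.29 ± 0.25 on the log2 scale (adjusted p = 1.48e-06), and the catalase gene CAT3 (AT1G20620) by 1.42 ± 0.24 (adjusted p = 0.00027).

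Heat shock genes rose with RB for 28 of 34, and 29 adjusted over the list alone (adjusted p = 2.23e-38, and adjusted p = 0.00702 with an estimated correlation). Xenobiotic genes rose for 14 of 15, and 14 adjusted over the list alone (adjusted p = 6.68e-30, and adjusted p = 0.0016 with an estimated correlation). Glutathione S-transferase genes rose for 16 of 23 and fell for 1, against 18 and 1 adjusted over the list alone (adjusted p = 3.75e-14, and adjusted p = 0.00702 with an estimated correlation). Tryptophan-derived defence genes rose for 12 of 13, and 12 adjusted over the list alone (median 2.22, adjusted p = 2.04e-16, and adjusted p = 0.0016 with an estimated correlation). Singlet oxygen-responsive genes rose for 11 of 18, and 11 adjusted over the list alone (adjusted p = 1.2e-09, and adjusted p = 0.0154 with an estimated correlation). All 7 root hair markers tested fell, and 7 adjusted over the list alone (median -4.19, adjusted p = 5.09e-12, and adjusted p = 0.01 with an estimated correlation). Aquaporin genes fell for 11 of 18 and rose for 1, with the same counts adjusted over the list alone (median -0.99, adjusted p = 7.13e-06, and adjusted p = 0.135 with an estimated correlation). Jasmonate genes rose for 8 of 25 and fell for 2, with the same counts adjusted over the list alone (adjusted p = 0.0095, and adjusted p = 0.0611 with an estimated correlation). The ROS-responsive zinc-finger, ERF and kinase genes rose for 9 of 14 and fell for 2, against 10 and 2 adjusted over the list alone (adjusted p = 0.000443, and adjusted p = 0.243 with an estimated correlation).

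**Figure D4:**
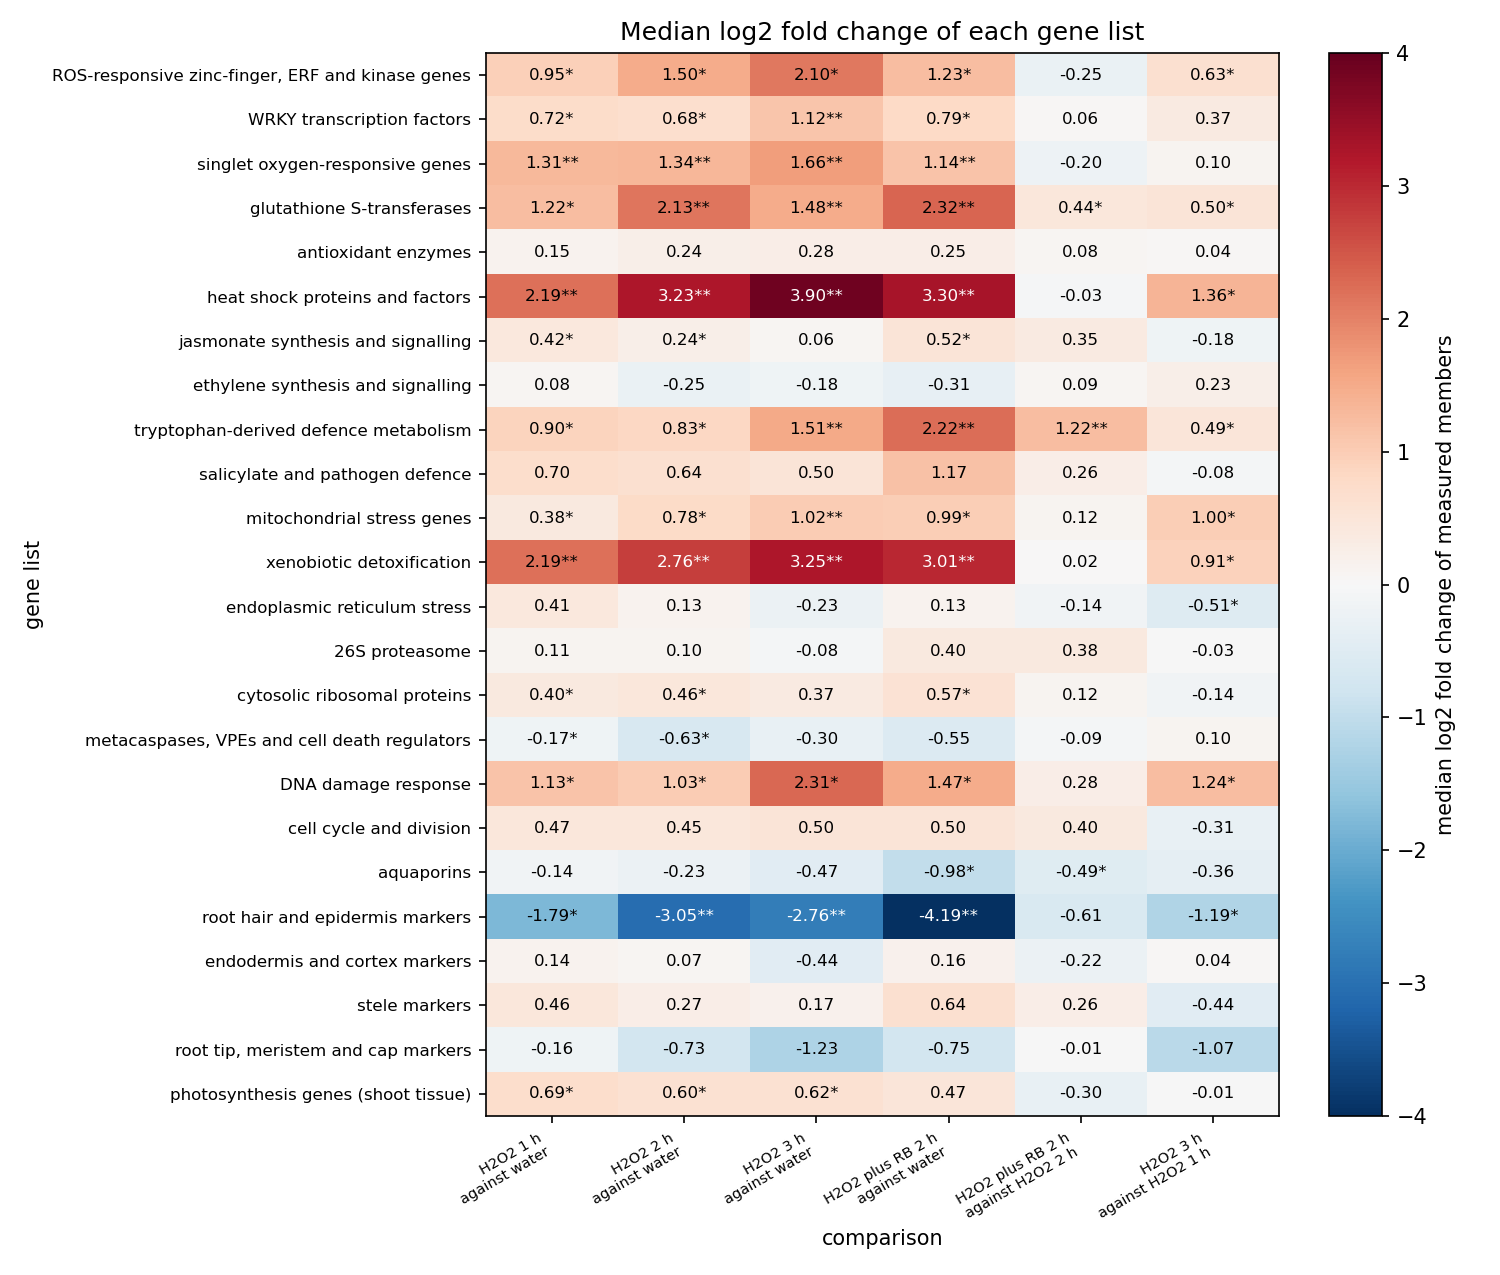
The colour and the number in each cell give the median log2 fold change of a gene list (rows, 24 lists) in a comparison (columns, 6), with 1 asterisk for a camera adjusted p under 0.05 with the preset correlation, a pair of asterisks where it also held with an estimated correlation, and colours that saturate at -4 and 4. Heat shock genes stood at 2.19, 3.23, 3.90 and 3.302 against water and at -0.03 between RB and H2O2 alone, where the tryptophan list stood at 1.22.

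The comparison of both 2 h treatments, H2O2 with and without RB, isolates what RB added at the same time and H2O2 dose. Genes of the pathway from tryptophan to camalexin rose, and genes for vegetative storage proteins and 4 of 18 aquaporins fell. CYP79B2 (AT4G39950), which turns tryptophan into its oxime, rose to 1153 ± 193 CPM from 320 ± 64.8 CPM (n = 3 per group, log2 1.85 ± 0.24, adjusted p = 0.000444). PAD3 rose to 178 ± 32.3 CPM from 36.5 ± 25.3 CPM (log2 2.22 ± 0.37, adjusted p = 0.00287). GSTU12 rose to 778.5 ± 92.4 CPM from 223 ± 31.7 CPM (log2 1.80 ± 0.28, adjusted p = 0.00155). The jasmonate-responsive storage protein gene VSP1 (AT5G24780) fell to 31.8 ± 7.40 CPM from 117 ± 21.2 CPM (log2 -1.90 ± 0.27, adjusted p = 0.000656). ERF72 fell to 116 ± 16.9 CPM from 314 ± 38.9 CPM (log2 -1.44 ± 0.24, adjusted p = 0.00273). The copper transporter gene COPT2 (AT3G46900) fell to 17.3 ± 7.95 CPM from 88.5 ± 19.8 CPM (log2 -2.46 ± 0.33, adjusted p = 0.000574).

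Between both 2 h treatments 74 genes were higher with RB and 169 lower. The calls numbered 130 without H2O2 2 h b (31 higher, 99 lower), 92 without H2O2 2 h c (21 higher, 71 lower), 149 without RB a (94 lower), 146 without RB b (34 higher, 112 lower) and 109 without RB c (48 higher, 61 lower). The cytochrome P450 gene CYP71A12 (AT2G30750) rose to 42.1 ± 6.57 CPM from 4.06 ± 1.58 CPM (log2 3.26 ± 0.46, adjusted p = 0.000656). AT3G22620 rose to 1012 ± 369 CPM from 265 ± 63.3 CPM (log2 1.93 ± 0.29, adjusted p = 0.00102), and AT5G48430 fell to 13.9 ± 1.08 CPM from 138.5 ± 24.9 CPM (log2 -3.32 ± 0.44, adjusted p = 0.000538). VSP2 (AT5G24770) fell to 4.33 ± 1.67 CPM from 35.2 ± 8.88 CPM (log2 -3.06 ± 0.37, adjusted p = 0.000413) and PIP2-4 fell by 1.64 ± 0.29 on the log2 scale (adjusted p = 0.00415). ERF109 fell by 1.39 ± 0.29 on the log2 scale (adjusted p = 0.0136), a call lost without H2O2 2 h c, without RB a and without RB c. The other sentinels tested did not pass, with HSP101 at log2 0.00 ± 0.24 (adjusted p = 0.999), BAP1 at -1.16 ± 0.32 (adjusted p = 0.0625, but called in 10 of 25 alternatives, among them DESeq2, thinning and without H2O2 2 h a, H2O2 3 h a or H2O2 3 h c), HSFA2 at -0.82 (adjusted p = 0.217) and GSTU24 at 0.68 (adjusted p = 0.393).

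The tryptophan-derived defence genes were the list that separated both treatments under either correlation. Of 13 genes 9 rose, and 12 adjusted over the list alone (median 1.22, adjusted p = 7.68e-24, and adjusted p = 0.000413 with an estimated correlation). Aquaporin genes fell for 4 of 18, and 7 adjusted over the list alone (median -0.49, adjusted p = 3.65e-08, and adjusted p = 0.335 with an estimated correlation). Glutathione S-transferase genes rose for 1 of 23, and 1 adjusted over the list alone (adjusted p = 0.00275, and adjusted p = 0.455 with an estimated correlation). The singlet oxygen-responsive list, fixed for the oxidant that the dye forms in light, had 1 gene that fell, against 2 that rose and 2 that fell adjusted over the list alone, and did not pass (median -0.20, adjusted p = 0.512). Heat shock genes did not pass as a set (median -0.03, adjusted p = 0.792), with 1 that rose, and 1 adjusted over the list alone. Of the jasmonate genes 1 rose and 2 fell, against 2 and 2 adjusted over the list alone (adjusted p = 0.435).

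**Figure D5:**
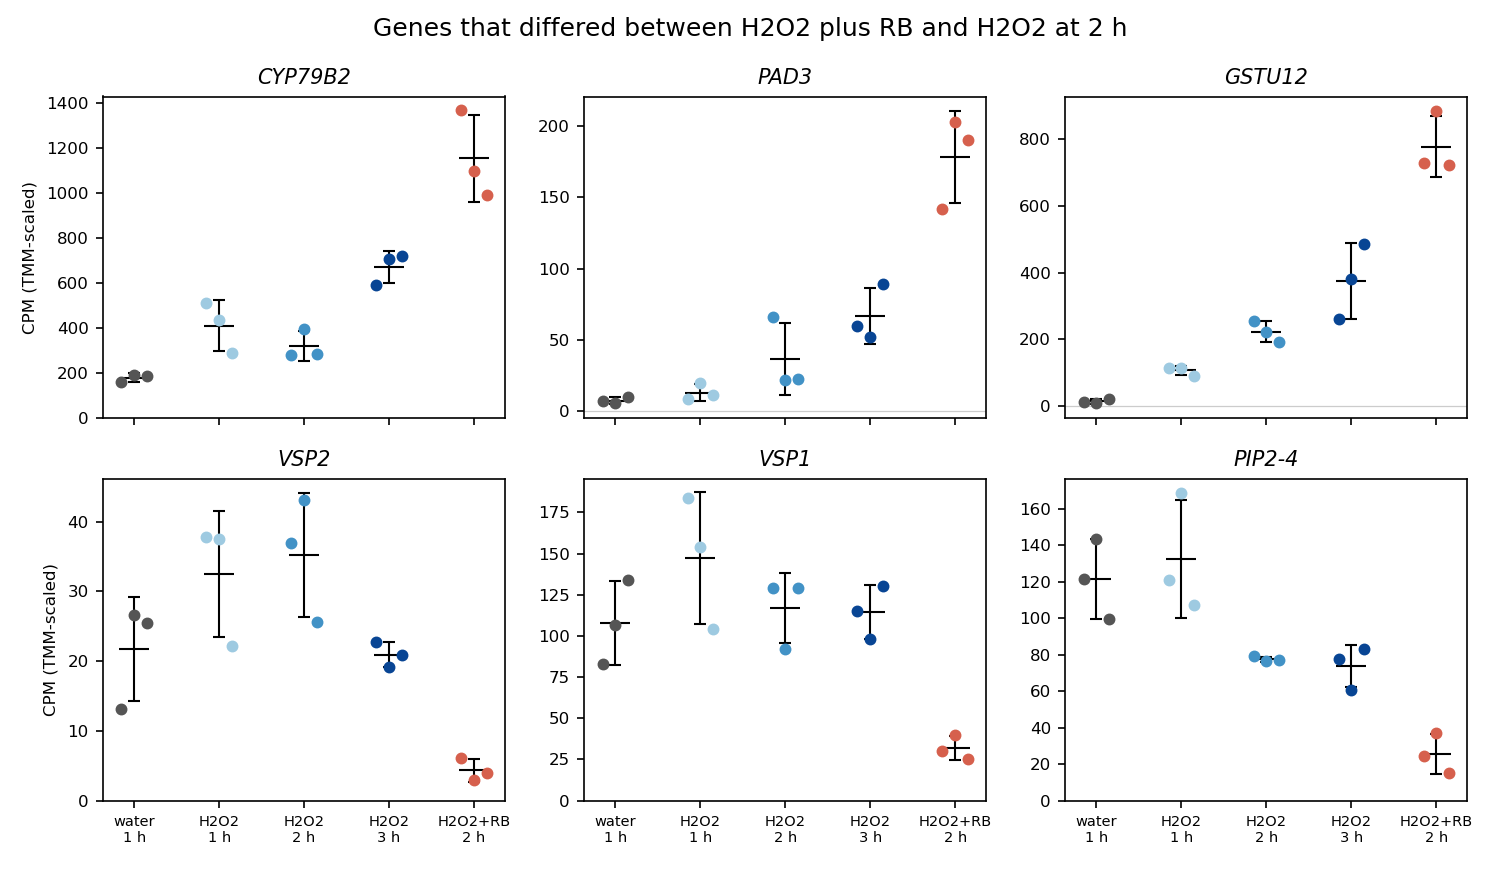
TMM-scaled CPM of CYP79B2, PAD3, GSTU12, VSP2, VSP1 and PIP2-4 is plotted per library on the vertical axis for the 5 groups, with points for the 3 libraries, a horizontal mark for the mean and bars for the SD. CYP79B2 stood at 320 CPM at 2 h of H2O2 and 1153 CPM with RB, and VSP1 at 117 CPM and 31.8 CPM.

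The responses to the 4 treatments shared part of their genes. At 1 h and 2 h of H2O2, 528 genes were higher in both and 213 lower in both, against 60.2 and 14.4 for independent lists, and 1 gene moved in opposite directions. Between 2 h and 3 h 837 were higher in both and 371 lower in both (149 and 67.7 for independent lists), with 2 in opposite directions. Between 2 h of H2O2 with and without RB 732 were higher in both and 359 lower in both (107 and 45.4 for independent lists), with 2 in opposite directions. Across genes, which are not independent replicates, log2 fold changes of this last pair correlated at r = 0.83 (covariance 0.89). All 4 comparisons share the 3 water libraries, and error in shared controls by itself makes fold changes correlate. Groups simulated without change gave r = 0.09 and a covariance of 0.01 for that pair and for each of the other 5. They were drawn around the means of these same water libraries, so the simulation left out that shared error and gives no baseline for r. The counts for independent lists leave it out too, so how much of the sharing comes from the common controls is not known. Between 1 h and 3 h 528 were higher in both, 191 lower in both and 8 opposite (106 higher and 43.6 lower for independent lists, r = 0.67). Between 3 h and 2 h with RB 868 were higher in both, 459 lower in both and 28 opposite (187 higher and 138 lower for independent lists, r = 0.67). In all 4 comparisons with water 428 genes were higher and 153 lower.

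Photosynthesis genes, a mark of shoot tissue, took 0.0850 ± 0.00449% of the counts in water and 0.115 ± 0.0167%, 0.105 ± 0.00424% and 0.101 ± 0.00967% at 1 h, 2 h and 3 h of H2O2 (mean ± SD, n = 3). With RB they took 0.0945 ± 0.0351%, with 0.134% in replicate c. Of 20 tested, 2, 4, 6 and 4 rose in the comparisons with water, and 9, 4, 6 and 4 adjusted over the list alone. The set passed at 1 h, 2 h and 3 h of H2O2 (adjusted p = 0.00309, 0.012 and 0.0284) and at none of these with an estimated correlation (adjusted p = 0.273, 0.397 and 0.523), and not with RB (adjusted p = 0.144). PSBP1 (AT1G06680) rose at 3 h by log2 1.51 ± 0.31 (adjusted p = 0.00108). Between RB and H2O2 alone 1 of these genes rose, and 2 adjusted over the list alone. There the list had a median of -0.30 and a mean of 0.04 (adjusted p = 0.435, test downward), and between 3 h and 1 h a median of -0.01 and a mean of 0.03 (adjusted p = 0.871).

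Of 30 antioxidant enzyme genes tested, 3, 6, 7 and 8 rose in the comparisons with water and 1, 1, 2 and 2 fell, and 3, 6, 7 and 9 rose adjusted over the list alone, with no set call (adjusted p = 0.318, 0.102, 0.0692 and 0.0725). The glutathione synthesis gene GSH1 (AT4G23100) rose by log2 1.21 ± 0.19 at 2 h (adjusted p = 0.000159) and 1.54 ± 0.19 at 3 h (adjusted p = 6.71e-06). WRKY factors rose for 3, 4 and 5 of 10 at 1 h, 2 h and with RB against water, and 6, 5 and 5 adjusted over the list alone (adjusted p = 0.00341, 0.000828 and 0.000492, and adjusted p = 0.105, 0.0777 and 0.0611 with an estimated correlation). At 1 h 1 WRKY factor fell adjusted over the list alone. Mitochondrial stress genes rose for 3, 3 and 4 of 11 in the same comparisons, and 3, 3 and 5 adjusted over the list alone (adjusted p = 0.0183, 0.000566 and 0.00139, and adjusted p = 0.143, 0.0684 and 0.0611 with an estimated correlation). With RB 1 of them fell, also adjusted over the list alone, and at 1 h 1 fell adjusted over the list alone. Their alternative dehydrogenase gene NDB2 (AT4G05020) rose by log2 1.48 ± 0.22 at 1 h (adjusted p = 0.000159).

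Cytosolic ribosomal protein genes rose for 4, 8 and 9 of 48 at 1 h, 2 h and with RB against water, and 8, 9 and 9 adjusted over the list alone (adjusted p = 0.00382, 0.000687 and 6e-05, and adjusted p = 0.273, 0.216 and 0.148 with an estimated correlation). At 3 h 9 rose and 4 fell, with the same counts adjusted over the list alone (adjusted p = 0.294). The DNA damage list rose for 1, 1 and 2 of 4 at 1 h, 2 h and with RB, and 2, 1 and 3 adjusted over the list alone (adjusted p = 0.025, 0.0336 and 0.0266, and adjusted p = 0.14, 0.161 and 0.148 with an estimated correlation). Between 1 h and 3 h 2 of its genes rose, and 2 adjusted over the list alone (adjusted p = 0.0456, and adjusted p = 0.209 with an estimated correlation). The cell death list of metacaspases, vacuolar processing enzymes and regulators fell for 2 and 3 of 10 at 1 h and 2 h, and 4 and 5 adjusted over the list alone (adjusted p = 0.0156 and 0.0489, and adjusted p = 0.0669 and 0.0986 with an estimated correlation). With RB 3 of these genes fell, and 3 adjusted over the list alone (adjusted p = 0.0593), and at 3 h 1 fell with a call not kept adjusted over the list alone (adjusted p = 0.501), so the set did not pass there. At 1 h its protease gene GAMMA-VPE (AT4G32940) fell by 1.496 ± 0.28 on the log2 scale, and KTI1, which codes for a protease inhibitor that restrains cell death, fell too.

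Ethylene genes gave no set call in the comparisons with water. They had medians of 0.08, -0.25, -0.18 and -0.31 and means of -0.13, 0.02, 0.17 and 0.23 at 1 h, 2 h, 3 h and with RB, with tests downward, downward, upward and upward (adjusted p = 0.123, 0.639, 0.904 and 0.954). Their receptor gene ETR2 (AT3G23150) fell by 1.11 ± 0.22 on the log2 scale at 1 h (adjusted p = 0.00256). At 3 h 4 ethylene genes rose and 3 fell, against 4 and 4 adjusted over the list alone. Aquaporin genes fell for 2, 4 and 6 of 18 at 1 h, 2 h and 3 h and rose for 2, 2 and 2 (4, 4 and 6 fell adjusted over the list alone), with a set test at adjusted p = 0.56, 0.103 and 0.113. TIP1-2 (AT3G26520) fell at 3 h to 1668 ± 421 CPM from 3931 ± 247 CPM (adjusted p = 0.00141). Endoplasmic reticulum stress genes rose for 2 of 12 at 1 h and fell for 2 at 3 h, against 3 and 2 adjusted over the list alone (adjusted p = 0.0573 and 0.672). At 3 h jasmonate genes rose for 8 of 25 and fell for 2, with the same counts adjusted over the list alone (adjusted p = 0.177).

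At 3 h against water, of 14 genes of the 26S proteasome 1 rose, a call not kept adjusted over the list alone, with a median of -0.08, a mean of -0.17 and a test upward (adjusted p = 0.903). Of 4 salicylate and pathogen defence genes 1 rose, and 1 adjusted over the list alone (adjusted p = 0.421). The root cap gene SMB (AT1G79580) was the 1 root tip marker of 2 that fell, and 1 adjusted over the list alone (log2 -1.89 ± 0.38, adjusted p = 0.000961, set test adjusted p = 0.2). As a set, the 7 endodermis and cortex markers tested did not pass (adjusted p = 0.791). As sets, cell cycle and division genes and stele markers, 5 tested of each, did not pass at 1 h (adjusted p = 0.291 and 0.316) or at 3 h (adjusted p = 0.799 and 0.731). At 1 h 1 of each rose, and 1 and 2 adjusted over the list alone. The cyclin gene CYCD3-1 (AT4G34160) rose by log2 1.64 ± 0.41 (adjusted p = 0.0137), a call lost without water a and without H2O2 1 h c, and a gene not tested with thinning. The xylem protease gene XCP1 (AT4G35350) rose by log2 1.39 ± 0.37 (adjusted p = 0.0219), a call lost without water a, water b, water c or H2O2 1 h b and with thinning.

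The authors' deposited table calls 702, 974, 363, 1566, 250 and 222 genes in the comparisons at 1 h, 2 h and 3 h against water, RB against water, RB against H2O2 alone, and 3 h against 1 h. The lowest absolute log2 fold change among the authors' calls was 1, 1, 1.12, 1, 1 and 1.09, while the edgeR calls here rest on adjusted p alone, so the 2 sets of numbers differ in threshold. By adjusted p under 0.05 alone, the authors' deposited table held 954 genes at 1 h, 1327 at 2 h, 2096 for RB against water and 285 for RB against H2O2 alone. Of the genes with an authors' call, edgeR also called 690, 965, 363, 1544, 214 and 222. Log2 fold changes in the authors' deposited table correlated with the edgeR values across tested genes at r = 0.99, 1.00, 1.00, 1.00, 1.00 and 0.99. At 3 h against water the authors' deposited adjusted p-values were under 0.05 for 363 genes, while BH adjustment of the p-values in the authors' deposited table gave 3125, and the corresponding numbers between 3 h and 1 h were 223 and 1382.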

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

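The comparisons and the splits of samples in this part were planned before the data were examined, and the genes named for opposite directions were chosen after their values were seen. Groups of 3 libraries were not tested for single libraries far from the others.

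H2O2 with and without RB at 2 h differed for 243 genes by the direct test between them in edgeR. Without samples of RB alone, a changed response to H2O2 cannot be told apart from an effect of RB itself. For 2 genes the effects of both treatments against water passed in opposite directions. AT4G25250 was lower with RB than in water and higher with H2O2 alone (log2 -1.24 and 1.73), a difference of -2.98 (adjusted p = 0.000656). AT1G24575 did the same (log2 -1.94 and 1.64), with a difference of -3.59 (adjusted p = 0.00314).

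The effects of 3 h and 1 h of H2O2 differed for 1383 genes by the direct test. For 8 genes both effects passed in opposite directions, all of them lower than in water at 1 h and higher at 3 h. The metallothionein gene MT2A (AT3G09390) went from log2 -1.89 at 1 h to 1.199 at 3 h, a difference of 3.09 (adjusted p = 5.02e-06), and the formate dehydrogenase gene FDH (AT5G14780) from -0.94 to 0.92 (difference 1.86, adjusted p = 6.9e-06). The defensin-like gene PDF1.4 (AT1G19610) went from -2.12 to 1.75 (difference 3.87, adjusted p = 6.07e-05), and the expansin-like gene EXLB1 from -1.55 to 0.67 (difference 2.22, adjusted p = 2.45e-05). The others were GSTF2, IVD, AT1G13990 and Rap2.6L, with differences of 1.95, 1.64, 1.94 and 1.79.

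The 6 samples of each comparison can be split into groups of 3 in 10 ways, too few for a share under 0.05, and in each comparison 1 of the 10 splits, the real one itself, reached its number of calls. In edgeR fits to those 6 samples the real split gave 710 calls at 1 h, 1125 at 2 h and 2639 at 3 h against water, 2182 for RB against water, 270 for RB against H2O2 alone and 848 for 3 h against 1 h. The highest of the other splits gave 0 calls in each comparison. Each other split mixes libraries of the compared groups, so real changes between these groups add to the spread within its parts. Few calls were therefore likely in such splits, and their counts do not show how many calls would arise without a treatment effect. At an unadjusted p under 0.05 the highest of the other splits gave 1757, 1354, 736, 265, 931 and 1001 genes, and the real ones 1838, 2298, 3661, 3183, 1197 and 2121. The split with 1757 put water a, water b and H2O2 1 h b, the 3 libraries of the 6 with the most counts, against the others. The split with 1354 did the same with water a, water b and H2O2 2 h a. Depth as the source of these differences was not tested.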

How the results depend on the processing

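Thinning, the log2 depth covariate and length offsets were chosen after the data were seen, and the other alternatives before. Each comparison's number of calls stayed within 1.5 times its value under RLE and upper-quartile scaling, no filter, a strict filter, DESeq2, the replicate block and length offsets. Over these 7 the calls ran from 873 to 1047 at 1 h, 1289 to 1435 at 2 h and 2502 to 3492 at 3 h of H2O2 against water, 1969 to 2182 for RB against water, 230 to 331 for RB against H2O2 alone and 1146 to 1533 for 3 h against 1 h. The block, the only fit that uses replicate letters, gave 946, 1366, 2894, 2055, 230 and 1284 calls in that order. Like totals did not mean the same genes. Of the 3048 main calls at 3 h, 3032, 2701, 2733, 2285, 2851, 2835 and 2342 kept their call and sign under the 7, in the order named. The strict filter tested 7551 genes. Length offsets kept 856 of 958 calls at 1 h, 1133 of 1392 at 2 h and 1862 of 2120 for RB against water. They kept 231 of 243 for RB against H2O2 alone and 1150 of 1383 for 3 h against 1 h. The smaller counts of list members that rose or fell were less stable. They left the bound of 1.5 times in 3 cases with RLE, 23 with upper-quartile scaling, 35 with no filter, 26 with the strict filter, 10 with DESeq2 and 16 with the block. They stayed within it in 285, 265, 253, 262, 278 and 272 cases, in that order.

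Thinned to equal depth, the 6 comparisons had 734, 1019, 1803, 1494, 150 and 770 calls, of which 487, 653, 1040, 839, 56 and 408 were higher and 247, 366, 763, 655, 94 and 362 lower. Of these calls, 650, 937, 1688, 1380, 132 and 694 were called with the same sign without thinning. Thinning left 6765 genes to test and took counts from the larger libraries, so depth limits these numbers. The log2 depth covariate gave 1368, 1803, 3665, 2683, 315 and 1822 calls in the 6 comparisons, more than the main fit in each. Among these were 546 lower genes at 1 h against water and 127 higher genes for RB against H2O2 alone. The cause was not tested. A fit to only the 6 samples compared gave 848 calls for 3 h against 1 h, 413 higher and 435 lower, with fewer samples behind the estimated spread.

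Leaving out 1 library at a time gave 577 to 1072 calls at 1 h (365 to 713 higher, 157 to 391 lower), 893 to 1512 at 2 h (577 to 981 higher, 291 to 561 lower), 2148 to 3227 at 3 h and 1586 to 2259 for RB against water. RB against H2O2 alone had 92 to 288 calls (21 to 98 higher, 61 to 202 lower), and 3 h against 1 h had 749 to 1492 (345 to 929 higher, 393 to 737 lower). With 1 library fewer a group has 2, so part of the fall is the smaller n, and for rises the cause was not tested.

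Of the 24 lists, 14, 14, 11, 13 and 3 passed camera with the preset correlation and 3, 5, 8, 6 and 1 with an estimated one, and for 3 h against 1 h 9 passed with the preset one and the lowest adjusted p with the estimated one was 0.0734. The value of UGT74E2 in H2O2 1 h against water changed from log2 -0.29 to 2.05 (adjusted p = 0.0392) without water a and to -1.0024 without water b. Water a had 15.9 CPM of this transcript. Among gene values named by rule, DESeq2 left 394 on the same side, with 5 weaker and 2 stronger, and thinning left 351, with 27 weaker and 2 stronger.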

Other observations

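Of the tests in this part, transcript length for the root hair markers and the removal of genes raised at 3 h were planned before their results were seen, and the others were chosen after. The product families were also chosen after their values were seen.

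Extensins are hydroxyproline-rich proteins of the cell wall. Of 28 tested genes whose product is an extensin or extensin-like protein, 12, 16, 20 and 17 fell at 1 h, 2 h and 3 h of H2O2 and with RB against water, with median log2 fold changes of -1.46, -1.96, -3.11 and -3.39. Between 1 h and 3 h 14 fell (median -2.33). Between both 2 h treatments the median was 0.15. Of 8 coatomer genes, whose products coat vesicles of the Golgi, 3 fell at 3 h against water and 4 between 1 h and 3 h. Of 4 nitrilase genes 3 rose at 3 h against water (median 2.42), and 2 between 1 h and 3 h (median 2.03).

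The markers of root hair and epidermis had a median log2 fold change of -2.76 at 3 h, and GL2, named here after its value was seen and expressed in the hairless cells of the epidermis, fell by 1.55 on the log2 scale. Transcript length as the whole cause was argued against, since medians of 10000 lists matched on length had a 2.5th percentile of -0.92 (-0.9208) and a lowest value of -2.74. A lower share of root hair cells would lower exclusive markers alike, and the members fell unequally, from -6.34 to -1.55 (chi-square test of heterogeneity over their edgeR values and SEs, p = 2.9e-09). That bound was ill-chosen, because markers that other cells also express fall less, so a lower share of these cells cannot be told apart from lower expression within them. A treatment effect on hair cell transcripts may therefore stand beside a loss of such cells.

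Fold changes at 3 h against water fell with transcript length across 9963 genes (Spearman -0.27), which are not independent replicates. The trend was not particular to 3 h: Spearman was -0.14 at 1 h, -0.24 at 2 h and -0.20 with RB against water. It was -0.24 for 3 h against 1 h and 0.05 for RB against H2O2 alone. Of the lists, only the root hair markers were compared with lists matched on length, so its part in other lists' changes was not tested. At 3 h the 1368 genes with transcripts under 1000 nt had a median log2 fold change of 0.48 and the 1049 over 3000 nt one of -0.50. Library depth, and GC content with abundance, were argued against as the whole cause at 3 h: the correlation was -0.28 (-0.2773) with log2 depth as a covariate and -0.23 (-0.2288) as a partial one. Over the 9 H2O2 libraries the trend with length fell with hours at rho = -0.4216 (two-sided permutation p = 0.278) and r = -0.51 (permutation p = 0.162, BH 0.324 over 2 relations). Without H2O2 1 h a and b, r was -0.26. These 2 were taken by order among libraries equally far from the middle time, so this value is no check on outlying libraries. The r of the trend with log2 total count was 0.24 (permutation p = 0.535). Exposure time as a cause thus stays open. RNA integrity was not tested.

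Thinned to equal depth, the libraries of 3 h of H2O2 had 11486, 10715 and 10854 genes detected, against 11715 to 12649 in the others. With total count as a covariate they had on average 1257 fewer than the other 12 (95% interval 717 to 1798), though the highest of them (11400) lay only 238 below the lowest other, RB c (11639, SD within groups 350.7). Without the 1615 genes raised at 3 h they had 1036 fewer than water, which decides little because removing genes for rising at 3 h favours a shortfall there. With water thinned further, by the share of counts these genes gained, 903 fewer remained over all genes (95% interval 256 to 1550), and 948 with total count as a covariate too (95% interval 293 to 1602), while H2O2 3 h a (11436) lay below the 3 water libraries (at least 11677) but above 1 h c, 2 h b, 2 h c and RB c thinned alike. Depth, induced genes taking the counts, and the 2 together were thus argued against as the whole cause of the gap to water, and RNA integrity was not tested.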
